A study of Homo sapiens with 12 samples.

How the data were processed

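Gene expression was measured in HK-2 cells, an immortalized line of human proximal tubule epithelium from the kidney, on 12 Affymetrix arrays. Per the labels' protocols, the cells grew in a DMEM and Ham's F12 medium with EGF, hydrocortisone, insulin, transferrin and selenite, were treated when nearly confluent, and gave total RNA that was converted to biotinylated cRNA. Each array held 1 sample. The labels name 4 groups of 3 biological replicates: a high dose of a compound called Nnm, or its vehicle control, for 24 h or 48 h. The name Nnm is used as the labels give it, and neither the dose nor the vehicle is specified further in the sources used here.

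The deposited table held 1 log2 expression value per probe set and array, made with GCRMA per the submitters' processing notes, with no version given. GCRMA corrects the background from probe sequence, normalizes arrays to one another and summarises the probes of a set. Because the values are already forced to similar distributions, with array medians between 2.91 and 2.98, a change shared by most genes would not be visible in them. Over which arrays the authors normalized is not given in the sources used here, and neither the scanner files nor detection calls were used here. The precision of each value is limited by the number of arrays.

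The table listed 54675 probe sets. Of these, 62 were manufacturer's control probe sets, which were left out of all tests. A probe set was tested if its log2 value was above 4 on at least 3 of the 12 arrays, and 22829 passed. The platform annotation named 1 gene for 41097 of all probe sets and several genes for 1801, while 11777 carried no name there. Symbols were updated through the RefSeq gene table of GRCh38.p14, which was used for names only. Of the tested probe sets, 19986 named 1 gene, 960 several and 1883 none, giving 10963 tested genes. Each gene was represented by the probe set with the highest mean over the 12 arrays among those naming that gene alone.

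All 12 arrays entered 1 linear model with 4 groups in limma 3.58.1 (lmFit, contrasts.fit and eBayes) under R 4.3.3, with 8 residual degrees of freedom. The contrasts were Nnm against control at 24 h, Nnm against control at 48 h, the difference between these Nnm effects, and control cells at 48 h against 24 h. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p given for a gene comes from limma. Standard deviations are over the 3 arrays of a group, and where levels are given for a gene the control mean comes first and the Nnm mean second. GCRMA values carry no detection flag, so where a group's mean lay under log2 4 the fold is given as at least the ratio of the brighter group's mean to that filter level, and both measured means are kept.

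A total of 34 gene lists with 624 entries was written from textbook knowledge, and 458 entries were tested. Of these lists, 32 had at least 2 tested members and were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with a correlation estimated from the residuals and fry, which asks whether the genes of a list move on balance one way, were run beside it. Fry called 8 lists at 24 h, 9 at 48 h and 0 in the other 2 contrasts, against 11, 9, 11 and 6 by camera. With the estimated correlation 0 lists were called in any contrast, and the lowest adjusted p was 0.538 at 24 h, 0.314 at 48 h, 0.394 for the difference and 0.729 for time in control cells. Members of a list that rose or fell were counted from the limma fit, first with the adjustment over all tested probe sets and then adjusted over the list alone.

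The genes named were chosen by rule. For each Nnm comparison these were the 10 largest rises and 10 largest falls among called genes whose Nnm and control arrays did not overlap and whose brighter group averaged at least log2 6. From each list, up to 4 called members with the largest change were taken, or the 2 members with the smallest p where fewer than 2 were called. For the other 2 contrasts the 5 largest called rises and falls would have been named, but no gene was called. HAVCR1, CLU, SPP1, CDKN1A, MDM2, GDF15, HMOX1, LCN2, CYP1A1 and CYP2E1 were named wherever measured, of which LCN2, CYP1A1 and CYP2E1 stayed under the filter. The filter, the contrasts, the lists, this rule and the alternatives not said below to be chosen later were set before the data were examined. RNF150, TXNIP at 24 h and in control cells, and the single arrays described were picked out after their values were seen.

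Arrays with the same replicate number deviated together from their group means. All 18 correlations between same-numbered arrays of different groups were above 0.1, from 0.162 to 0.669, against a median of -0.208 over the 36 pairs with different numbers. By this check, which comes from the data and not from the labels, the numbers paired the samples. Counts with the replicate number as a block are given for probe sets and for members of the lists called at 24 h or 48 h. They are also given for the p53 list, for the kidney injury list at 48 h, and for genes named as not passing where the block called them. Called genes that lost their call with a block within each time are given as totals only, in the part on processing. No pair of arrays was identical, the highest correlation being 0.991. The labels call the replicates biological and say no more about how they were separated.

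Both Nnm arrays numbered 2 lay near the control arrays. They were kept in the planned fit, and counts without them, chosen after seeing the data, stand beside it. Because they were picked for lying near the controls, leaving them out favours a larger Nnm effect and a smaller spread. The calls and p-values of fits without them therefore describe the remaining arrays and do not test the Nnm effect. Other alternatives were no filter, a filter at log2 6, a further quantile normalization, median centring, trend and robust eBayes, array weights, the replicate block, each array left out in turn, probe sets with the suffix x or s left out, 1 probe set per gene, a fold of at least 2, an adjusted p under 0.01, the compared arrays alone and a t-test per probe set. In data simulated for the 24 h contrast over 22829 probe sets, the fit recovered 40% of changes of log2 1, 80% of log2 2, 90% of log2 3 and 100% of log2 4, 50 probe sets each, with 13 false calls. Only these probe sets were changed, and each probe set had the same spread on every array. The shares recovered therefore need not hold for the real contrast. In a simulated 24 h contrast over 10963 genes, camera recovered 3 of 3 shifted lists with 0 calls among 21 unshifted ones. With an estimated correlation it also recovered 3 of 3. The genes were drawn independently of one another, so this simulation cannot tell how often correlated genes give false list calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.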

Results

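Expression was profiled in HK-2 cells treated with a high dose of Nnm or with vehicle for 24 h or 48 h, with 3 biological replicates in each of the 4 groups. The series belongs to a wider project on compounds toxic to the kidney, and its comparisons ask which transcripts Nnm changed at each time. Between 22023 and 22228 probe sets were above log2 4 on each array, and array medians lay between 2.91 and 2.98. The first principal component held 57.4% of the variance over the arrays. It placed the 6 control arrays between -49.6 and -44.2 and Nnm replicates 1 and 3 of both times between 68.6 and 87.8. Nnm replicate 2 lay at -16.1 at 24 h and at -19.8 at 48 h, nearer to the control arrays, with which it correlated at 0.974 and 0.977 against 0.938 and 0.947 with the other Nnm arrays of its time.

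**Figure D1:**
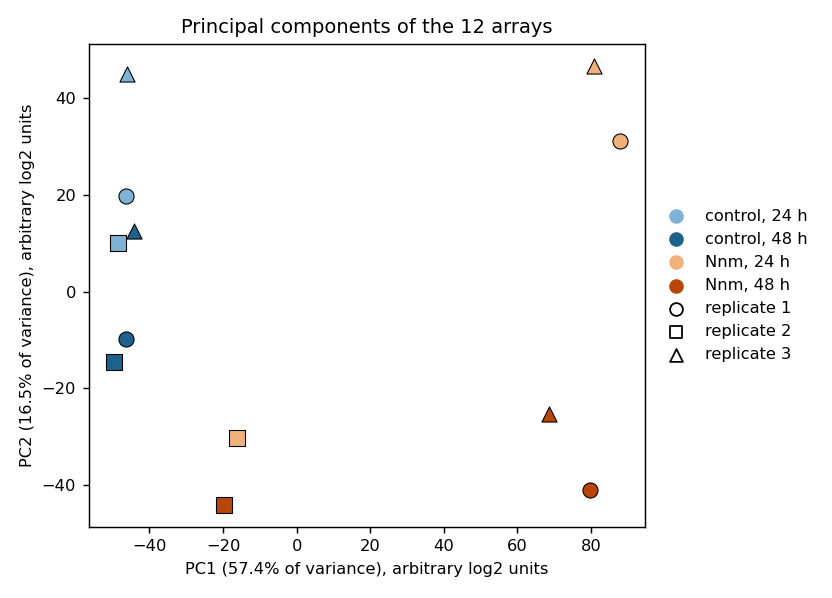
Principal components 1 and 2 of the log2 values of the 12 arrays, 1 point per array, in arbitrary log2 units, with colours for the group and symbols for the replicate number. Nnm replicates 1 and 3 stand at 68.6 to 87.8 on the first component, and both Nnm arrays numbered 2 stand at -16.1 and -19.8.

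Nnm against control at 24 h. SLC16A14 and SLC16A9, members of the monocarboxylate transporter family, and the dehydrogenase DHRS2 lay under the filter level in control cells and rose with Nnm. The log2 level of SLC16A14 went from 2.67 ± 0.39 to 9.63 ± 1.82 (SD, n = 3 arrays each), at least 49.6-fold (adjusted p = 0.00453). DHRS2 rose at least 13.6-fold, to 7.76 ± 2.83 (adjusted p = 0.0243), and SLC16A9 at least 9.30-fold, to 7.22 ± 2.09 (adjusted p = 0.0164). SLC7A11, the cystine transporter that feeds glutathione synthesis, rose from 7.02 ± 0.21 to 10.19 ± 1.99 (adjusted p = 0.0310). NRG1, a growth factor of the EGF family, went from 9.21 ± 0.41 to 5.68 ± 1.76 (adjusted p = 0.0495).

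Among the other large rises at 24 h were C5AR1, the receptor for complement fragment C5a, from 3.82 ± 0.34 to 8.17 ± 1.29, and ARRDC4, an arrestin-domain relative of TXNIP, at least 6.84-fold. PCLO, a presynaptic scaffold gene, rose by 4.22 on the log2 scale, the histone demethylase gene KDM7A by 3.55 and GKAP1 by 3.16, while TSHZ1 rose at least 4.76-fold. The falls included PLK2, a polo-like kinase, from 12.07 ± 0.22 to 9.36 ± 1.31, and the keratin KRT20, which fell by 2.73. TBL3 and POP1, which take part in RNA processing, fell by 2.91 and 2.69, and GCDH, a mitochondrial enzyme of lysine breakdown, fell by 2.70. ZBED10P fell by 3.17, ZFHX4-AS1 at least 7.30-fold, LINC00472 at least 6.38-fold and CBLN2, a secreted synaptic protein gene, at least 5.05-fold. These adjusted p-values lay between 0.0110 and 0.0446.

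In camera at the preset correlation with all arrays, ribosome biogenesis genes had the lowest list p at 24 h. Fry gave it to glucocorticoid targets (adjusted p = 7.07e-04 against 0.00244) and camera without the Nnm arrays numbered 2 to NRF2 targets (1.79e-04 against 8.89e-04). Of 16 ribosome biogenesis genes measured, 9 fell and 0 rose, and 15 fell when adjusted over the list alone and 12 with the replicate number as a block over all arrays (the block), among them BYSL by 1.49, RRS1 by 1.40 and MRTO4 by 1.08 on the log2 scale. The list was called lower by camera (median -0.74, adjusted p = 8.47e-06, and adjusted p = 0.538 with an estimated correlation). Of 22 oxidative phosphorylation genes 7 fell (9 adjusted over the list alone, 11 with the block), including SDHA by 1.16, NDUFS1 by 1.04 and CYC1 by 0.98, with a camera adjusted p of 2.19e-04 and adjusted p = 0.604 with an estimated correlation. In sterol metabolism, 4 of 18 cholesterol genes fell (12 adjusted over the list alone, and with the block 10 while 1 rose), such as ACAT2 by 1.66, NSDHL by 1.07 and SQLE by 0.87 (camera adjusted p = 4.97e-04, and adjusted p = 0.628 with an estimated correlation). Of 9 fatty acid synthesis genes 3 fell (6 adjusted over the list alone, and with the block 5 while 1 rose), namely FASN by 1.31, the lipogenic regulator SREBF1 by 1.13 and ACSS2 by 0.96 (camera adjusted p = 0.0260, and adjusted p = 0.604 with an estimated correlation).

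Camera also called the lists of excision repair and DNA replication lower at 24 h, and did not call homologous recombination and Fanconi repair (camera adjusted p = 0.679, 1 of 12 fell). In the list of base excision, nucleotide excision and direct repair, 5 of 17 fell (7 adjusted over the list alone, and with the block 7 while 1 rose), including the helicase gene ERCC2 by 1.62, the glycosylase gene MPG by 0.92 and ERCC1 by 0.79 (camera adjusted p = 0.00414, and adjusted p = 0.628 with an estimated correlation). Of 24 DNA replication genes 3 fell, CDC45 by 1.17, MCM4 by 0.90 and TYMS by 0.80. Adjusted over the list alone, 5 fell and 1 rose, and with the block 6 and 1 (camera adjusted p = 0.0155, and adjusted p = 0.802 with an estimated correlation). The median change of the replication list was -0.69 and -0.56 in Nnm replicates 1 and 3 and 0.03 in Nnm replicate 2.

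Camera called 5 lists higher at 24 h. Targets of NRF2, the regulator of antioxidant genes, had 3 of 18 members risen (12 adjusted over the list alone, also 12 with the block), in the first count SLC7A11, the thioredoxin reductase gene TXNRD1 by 1.97 and the quinone reductase gene NQO1 by 1.19 (camera adjusted p = 4.97e-04, and adjusted p = 0.604 with an estimated correlation). HMOX1, which encodes the heme-degrading heme oxygenase, measured 8.02 ± 0.24 to 10.82 ± 2.75 and did not pass (adjusted p = 0.0875), but was called with the block (0.0394). It stood at 12.05 and 12.74 in Nnm replicates 1 and 3 and at 7.67 in Nnm replicate 2. Of 14 interferon response genes 4 rose (also 4 adjusted over the list alone, 5 with the block), OAS1 by 1.62, IFIT2 by 1.49, IFIH1 by 1.31 and IFI44 by 0.95 (camera adjusted p = 0.0218, and adjusted p = 0.604 with an estimated correlation). Of 10 glucocorticoid targets 4 rose, and 4 adjusted over the list alone (with the block 4 rose and 1 fell), including TSC22D3 by 1.90 and GLUL by 1.15 (camera adjusted p = 0.0369, and adjusted p = 0.538 with an estimated correlation). In 2 more lists called higher, 0 of 26 ATF4 and amino acid response genes and 0 of 8 metallothionein and zinc export genes passed, also when adjusted over the list alone. With the block 7 ATF4 genes rose, among them CTH (adjusted p = 0.0309), and 1 fell, and 1 metallothionein list gene rose. Their camera adjusted p was 0.0496 and 0.0238, and adjusted p = 0.802 and 0.802 with an estimated correlation. The median change of the ATF4 list was 1.24 and 0.97 in Nnm replicates 1 and 3 and -0.19 in Nnm replicate 2.

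In the fit with all arrays, 3 of 23 p53 targets and 1 of 19 kidney injury genes were called at 24 h. Of the p53 targets, PPM1D rose by 1.11 while BAX fell by 0.67 and TRIAP1 by 0.96, and the list was not called (camera adjusted p = 0.971). Adjusted over the list alone, 1 rose and 1 fell, and with the block 1 and 4. CDKN1A, the cell cycle inhibitor p21, measured 9.58 ± 0.15 to 9.61 ± 1.04 (adjusted p = 0.981), MDM2 8.71 ± 0.03 to 8.96 ± 0.35 (adjusted p = 0.304) and the stress cytokine GDF15 10.46 ± 0.07 to 11.71 ± 2.05 (adjusted p = 0.356). Of the kidney injury genes, CLU, which encodes clusterin, rose by 0.66 (adjusted p = 0.0414) and 0 passed when adjusted over the list alone. HAVCR1, the injury marker KIM-1, measured 11.54 ± 0.11 to 10.89 ± 0.65 (adjusted p = 0.292) and SPP1 14.98 ± 0.10 to 15.09 ± 0.06 (adjusted p = 0.533). More were called when the Nnm arrays numbered 2 were left out, with 9 p53 targets risen and 4 fallen and 2 kidney injury genes risen and 4 fallen, while neither list was called (camera adjusted p = 0.462 and 0.556). In that fit GDF15 was called higher by 2.42 (adjusted p = 8.62e-05), CDKN1A by 0.62 (0.0398) and MDM2 by 0.43 (0.0125), and HAVCR1 was called with a change of -1.01 (0.00584). The arrays left out were picked for lying near the controls, so these p-values do not test the genes. With all arrays the chemokine CXCL8 fell by 2.44, and the matrix genes CCN1 and THBS1 fell by 2.02 and 1.70. Of the cell type markers tested, 4 of fibroblasts, 4 of podocytes, 2 of distal nephron and 1 of endothelial cells, 0 were called by limma, and 1 of distal nephron was when adjusted over its list alone. With the block 1 each of fibroblasts, podocytes and distal nephron was called.

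In total 3366 of 22829 probe sets were called at 24 h by limma, 1671 higher and 1695 lower, and 1657 of them had changed at least 2-fold. The 3 Nnm and 3 control arrays did not overlap for 37.2% of the tested probe sets, where chance gives 10%. The count was 6700 with the replicate number as a block over all arrays and 2415 with a block within each time, and it was 10730 without the Nnm arrays numbered 2. It moved to 86, 8683 and 192 without Nnm replicate 1, 2 and 3 and to 404, 1973 and 81 without control replicate 1, 2 and 3 of 24 h. Without the Nnm arrays numbered 2, 16 of 26 ATF4 genes and 13 of 18 NRF2 targets rose while 1 and 2 fell, and HMOX1 was higher by 4.38. In that fit the interferon and glucocorticoid lists were no longer called (camera adjusted p = 0.124 and 0.178), although their medians did not shrink, at 0.57 against 0.53 and 1.03 against 0.89. The fatty acid synthesis list lost its call with the block over all arrays or within each time (camera adjusted p = 0.0671 and 0.0764), and the glucocorticoid list with the first of these (0.0539). Fry did not call DNA replication (adjusted p = 0.190), ATF4 (0.401) or metallothioneins (0.0600).

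**Figure D2:**
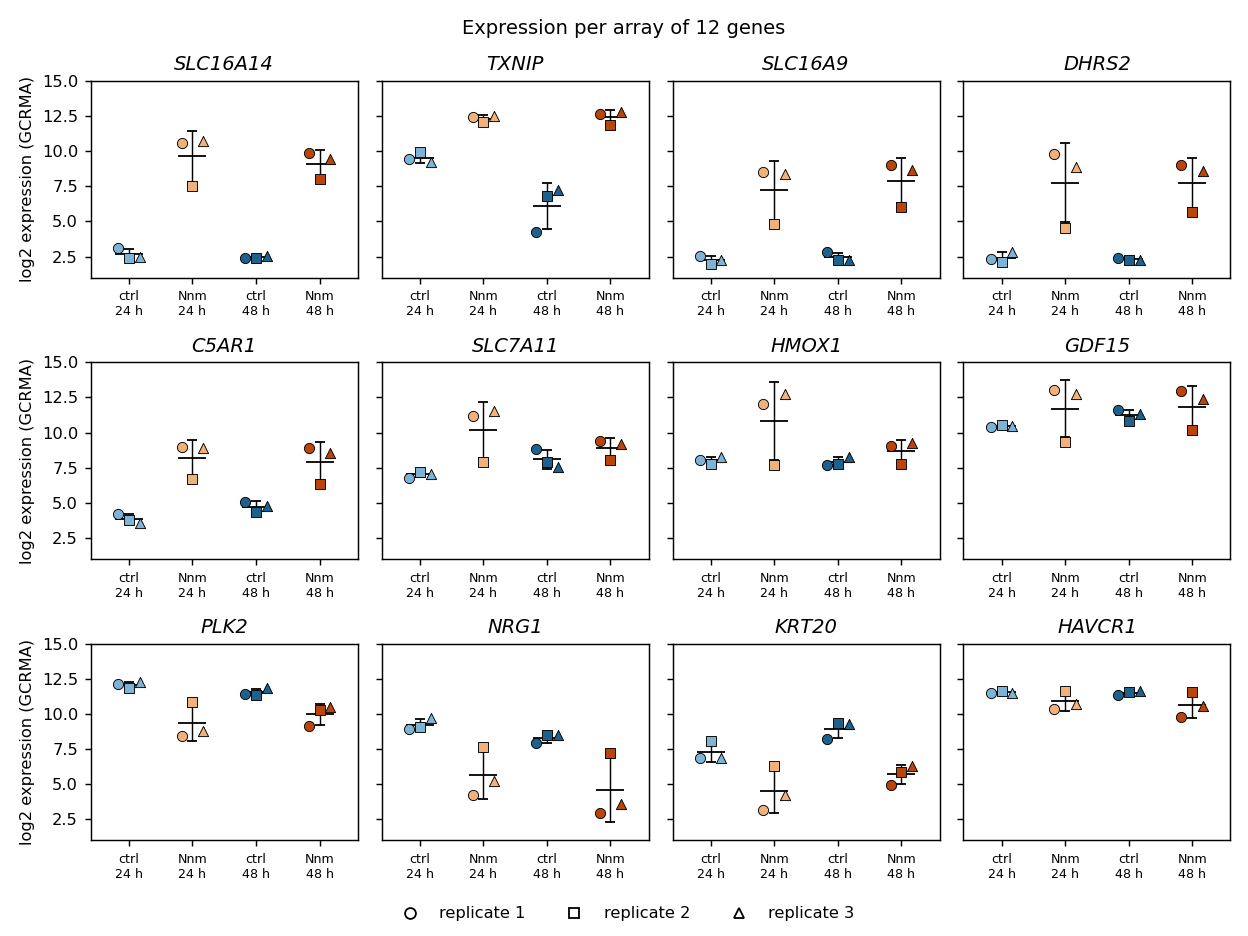
Log2 expression (GCRMA) of 12 genes on each of the 12 arrays, by group, with symbols for the replicate number, horizontal lines for the mean of 3 arrays and bars for 1 SD. SLC16A14 lies at 7.53 or above on every Nnm array, while HMOX1 at 24 h lies at 12.05 and 12.74 in Nnm replicates 1 and 3 and at 7.67 in Nnm replicate 2.

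Nnm against control at 48 h. TXNIP, the thioredoxin-interacting protein that restrains glucose uptake, stood higher in all 3 Nnm arrays and went from 6.09 ± 1.63 to 12.44 ± 0.50 (SD, n = 3 arrays each), a rise of 6.35 on the log2 scale (adjusted p = 0.00262). Its Nnm level was similar at 24 h, and its control level was higher there, though limma did not call that difference. In the measured means a lower control level makes up part of the 48 h difference. Whether that lower level is more than spread between arrays was not settled. SLC16A14 rose at least 34.9-fold, to 9.12 ± 0.95 (adjusted p = 0.00388), SLC16A9 went from 2.45 ± 0.31 to 7.91 ± 1.61 (adjusted p = 0.0133) and DHRS2 rose at least 13.4-fold (adjusted p = 0.0245). RSPO3, a secreted enhancer of WNT signalling, rose from 5.19 ± 0.15 to 9.48 ± 1.98 (adjusted p = 0.0138), and G0S2, an inhibitor of triglyceride lipase, from 8.09 ± 0.63 to 11.99 ± 2.18 (adjusted p = 0.0227). The long noncoding RNA UCA1 fell at least 9.45-fold (adjusted p = 0.0235), and KRT20 fell from 8.95 ± 0.63 to 5.71 ± 0.68 (adjusted p = 0.0238).

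Further rises at 48 h were PCLO by 3.70 and C5AR1 by 3.22 on the log2 scale, GAS1, a membrane protein gene named for growth arrest, at least 5.76-fold, and SHISA2 at least 8.87-fold. Further falls were ZBED10P by 3.08, ZFHX4-AS1 by 3.03, CCDC146 by 2.99, DNAJC30 by 2.46, B3GALT6 by 2.44, SRBD1 by 2.34 and PFKFB2, a regulator of glycolysis, by 2.42, with CBLN2 lower at least 4.12-fold. Their adjusted p-values ran from 0.00613 to 0.0498.

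Camera at the preset correlation called oxidative phosphorylation, cholesterol, fatty acid synthesis and fatty acid oxidation lists lower at 48 h. Of 22 oxidative phosphorylation genes 8 fell and 17 fell when adjusted over the list alone and 13 with the block, including ATP5MC1 by 1.27, NDUFS1 by 1.19, SDHA by 1.17 and CYC1 by 1.02 (camera adjusted p = 6.34e-10, and adjusted p = 0.314 with an estimated correlation). Of 18 cholesterol genes 4 fell (9 adjusted over the list alone, 11 with the block), with ACAT2 lower by 1.48, NSDHL by 1.04 and LSS by 1.03 (camera adjusted p = 2.82e-05, and adjusted p = 0.5002 with an estimated correlation). Of 9 fatty acid synthesis genes 3 fell, FASN by 1.28, SREBF1 by 1.19 and ACLY by 0.64. In all 5 fell and 1 rose when adjusted over the list alone, and the same numbers with the block (camera adjusted p = 0.0330, and adjusted p = 0.5002 with an estimated correlation). In fatty acid oxidation 4 of 14 genes fell, among them the dehydrogenase genes ACADS by 1.37 and ACADM by 0.67, and PDK4, a kinase that inhibits pyruvate oxidation, rose by 1.11. Adjusted over the list alone, 6 fell and 1 rose, and with the block 5 and 1 (camera adjusted p = 0.0363, and adjusted p = 0.353 with an estimated correlation). The kinase gene PDK1 fell by 1.64 and the glycolytic genes TPI1 and PGK1 by 0.75 and 0.67.

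Histone genes of the clusters, which are transcribed mainly during DNA synthesis, had 4 of 6 members fallen at 48 h, 6 adjusted over the list alone and 5 with the block. H1-2 fell at least 1.91-fold, H2BC9 by 1.39 and H2BC12 by 0.99 on the log2 scale (camera adjusted p = 2.91e-04, and adjusted p = 0.314 with an estimated correlation). Of 16 ribosome biogenesis genes 3 fell (also 3 adjusted over the list alone, 4 with the block), BYSL by 0.88, MRTO4 by 0.67 and WDR12 by 0.67 (camera adjusted p = 0.00276, and adjusted p = 0.540 with an estimated correlation). Of 12 homologous recombination and Fanconi repair genes 4 rose (and 6 adjusted over the list alone, also 6 with the block), such as the nuclease gene EXO1 by 1.16, RMI2 by 1.06 and CHEK1 by 0.72 (camera adjusted p = 0.0189, and adjusted p = 0.592 with an estimated correlation). The DNA replication genes CDT1, CCNE2 and RFC3 rose by 1.29, 0.92 and 0.60, 3 of 24 in that list, 5 adjusted over the list alone and 6 with the block, and the list was not called (camera adjusted p = 0.0789).

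Of 14 interferon response genes 4 rose at 48 h (5 adjusted over the list alone, also 5 with the block), OAS1 by 2.01, IFIT2 by 1.91, IFIT1 by 1.28 and IFI44 by 1.18 (camera adjusted p = 0.00222, and adjusted p = 0.314 with an estimated correlation). Of 18 NRF2 targets 2 rose (3 adjusted over the list alone, also 3 with the block), TXNRD1 by 1.58 and NQO1 by 1.34 (camera adjusted p = 0.0187, and adjusted p = 0.752 with an estimated correlation). HMOX1 measured 7.90 ± 0.33 to 8.68 ± 0.81 (adjusted p = 0.647), and CDKN1A 9.37 ± 0.42 to 9.48 ± 1.12 (adjusted p = 0.921). GDF15 measured 11.25 ± 0.38 to 11.84 ± 1.48 (adjusted p = 0.703) and HAVCR1 11.52 ± 0.14 to 10.63 ± 0.92 (adjusted p = 0.178). MDM2 measured 8.71 ± 0.01 to 8.78 ± 0.11 (adjusted p = 0.809), CLU 13.36 ± 0.23 to 13.94 ± 0.09 (adjusted p = 0.0696, called with the block at 0.0213) and SPP1 15.11 ± 0.05 to 14.95 ± 0.15 (adjusted p = 0.386). With the Nnm arrays numbered 2 left out, GDF15 was called higher by 1.42 (adjusted p = 0.00172), HMOX1 by 1.25 (0.00430) and CDKN1A by 0.76 (0.0204), and HAVCR1 with a change of -1.37 (0.00150), while MDM2, CLU and SPP1 were not called. In that fit 7 p53 targets rose and 3 fell, and 5 kidney injury genes rose and 4 fell, and neither list was called. Its p-values do not test these genes, since the arrays left out were picked for lying near the controls. With all arrays, of 23 p53 targets DDB2 rose by 0.93 and 0 passed when adjusted over the list alone, while 2 rose and 2 fell with the block (camera adjusted p = 0.893). Of 19 kidney injury genes IL18 rose by 0.78 and TIMP1 by 0.44, with 3 risen and 1 fallen when adjusted over the list alone and 4 and 1 with the block (camera adjusted p = 0.779). Of the 11 cell type markers tested, 0 were called by limma, and 1 of podocytes and 1 of distal nephron were when adjusted over their lists alone, and 1 of fibroblasts and 1 of podocytes with the block.

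In total 2323 of 22829 probe sets were called at 48 h by limma, 1310 higher and 1013 lower, and 1217 of them had changed at least 2-fold. Which side held more depended on the normalization, with 1225 higher and 1143 lower after a further quantile normalization and 1114 higher and 1279 lower after median centring. Nnm and control arrays did not overlap for 34.8% of the tested probe sets, where chance gives 10%. The count was 5046 with the replicate number as a block over all arrays and 9605 without the Nnm arrays numbered 2. It moved to 243, 6117 and 207 without Nnm replicate 1, 2 and 3 of 48 h and to 302, 815 and 403 without control replicate 1, 2 and 3 of 48 h. It was 4607 without Nnm replicate 2 of 24 h and 1414 without control replicate 1 of 24 h. Without the Nnm arrays numbered 2, 15 of 18 NRF2 targets and 14 of 26 ATF4 genes rose. The recombination and fatty acid synthesis lists were no longer called (camera adjusted p = 0.0700 and 0.0754), although their medians did not shrink, at 0.52 against 0.48 and -0.48 against -0.40. Fatty acid synthesis also lost its call with a block over all arrays or within each time (0.0829 and 0.0913), and a block within each time ended the call of the fatty acid oxidation list (0.0636). Fry did not call the NRF2 targets (adjusted p = 0.0768).

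**Figure D3:**
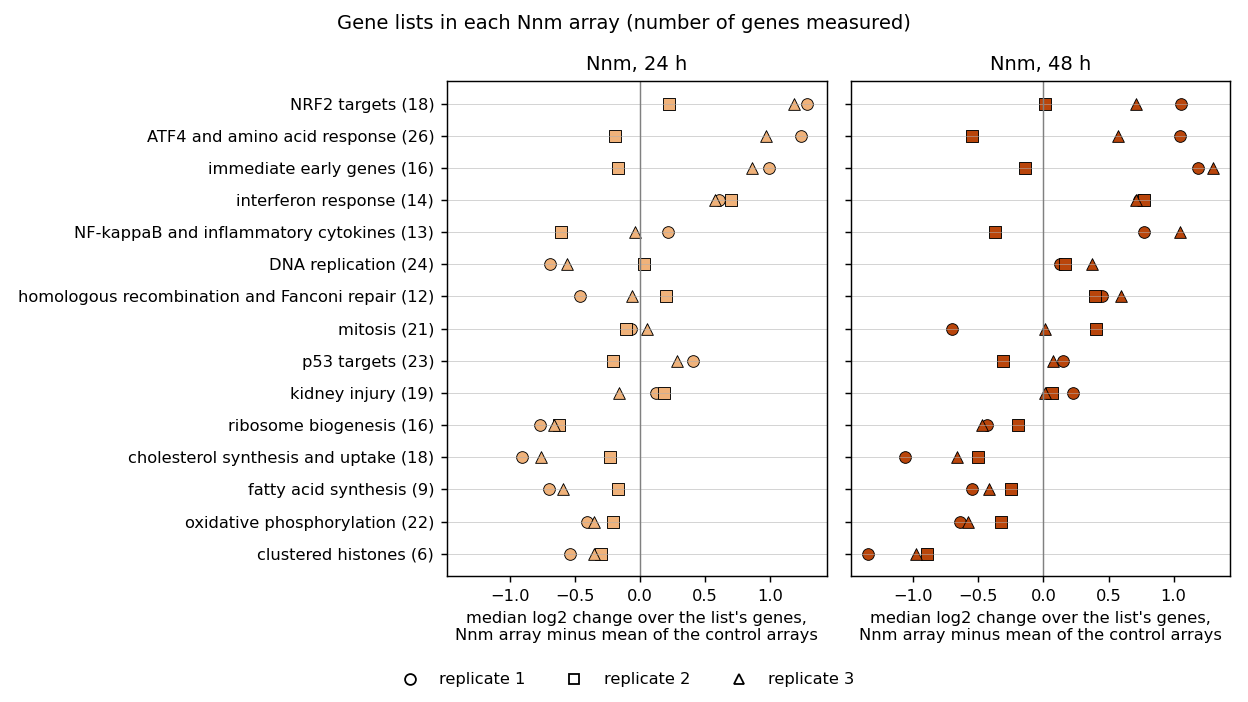
Median log2 change of 15 gene lists in each Nnm array against the mean of the 3 control arrays of its time, at 24 h and 48 h, with the number of genes measured beside each list and symbols for the replicate number. In the ATF4 list at 24 h Nnm replicates 1 and 3 lie at 1.24 and 0.97 and Nnm replicate 2 at -0.19, while in the interferon list the 3 arrays lie at 0.61, 0.70 and 0.58.

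Nnm effect at 48 h against 24 h. At both times 582 probe sets were called higher and 496 lower, and 0 were called in opposite directions. Without the Nnm arrays numbered 2 these were 3232 higher and 3096 lower at both times, and 220 called in opposite directions. Across the tested probe sets, which are not independent replicates, the log2 changes at 24 h and 48 h correlated at 0.773. Deviations of same-numbered arrays from their group means correlated between the times, at 0.508 to 0.669 in Nnm arrays and 0.480 to 0.582 in control arrays, so part of this agreement can come from the shared replicates, and how large a part was not tested. No gene was called for a difference between the effects, and fry called 0 lists where camera at a preset correlation called 11. Among the lists, DNA replication genes went from a median change of -0.48 at 24 h to 0.24 at 48 h, a median difference of 0.63 (camera adjusted p = 1.71e-09, and adjusted p = 0.394 with an estimated correlation). Of its members 0 of 24 passed, also when adjusted over the list alone. The recombination and Fanconi repair list had a median difference of 0.67 (camera adjusted p = 1.63e-04, and adjusted p = 0.394 with an estimated correlation). That of clustered histones was -0.74 (camera adjusted p = 0.00141, and adjusted p = 0.394 with an estimated correlation), where 1 of 6 passed when adjusted over the list alone.

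Single genes of this contrast had wide errors. The chemokine gene CCL20 had a difference of 3.86 (adjusted p = 0.780), SLC7A11 of -2.38 (adjusted p = 0.780) and CXCL8 of 2.10 (adjusted p = 0.780), with standard errors of 1.15, 1.14 and 0.83. In all, limma called 0 of 22829 probe sets, with 1418 at an unadjusted p under 0.05, and also 0 with the replicate number as a block. Without the Nnm arrays numbered 2 it called 2556, 1500 of them higher and 1056 lower, and with only 1 of them left out it called 1028 without the 24 h array and 102 without the 48 h array.

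Control cells at 48 h against 24 h. Camera at a preset correlation called 6 lists for time in control cells, while fry and an estimated correlation called 0, and no single gene passed. The mitosis list had a median change of -0.62 over 21 genes (camera adjusted p = 1.49e-09, and adjusted p = 0.729 with an estimated correlation). The DNA replication list had one of -0.38 over 24 genes (camera adjusted p = 6.59e-07, and adjusted p = 0.729 with an estimated correlation). Recombination and Fanconi repair genes changed by -0.39 (camera adjusted p = 0.00353, and adjusted p = 0.729 with an estimated correlation), with 3 of 12 passing when adjusted over the list alone and 0 in the 5 other called lists. CDC20, an activator of anaphase, had a change of -0.94 (adjusted p = 0.426) and CDC6, which loads the replicative helicase, of -0.97 (adjusted p = 0.444). Ribosome biogenesis genes at -0.25 and metallothioneins at -0.25 were called lower and ATF4 genes at 0.22 higher (camera adjusted p = 0.0140, 0.0140 and 0.0395, and adjusted p = 0.729, 0.729 and 0.894 with an estimated correlation). TXNIP stood at 9.55 ± 0.37 at 24 h and 6.09 ± 1.63 at 48 h, a change of -3.46 (adjusted p = 0.248).

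By limma 0 of 22829 probe sets were called in control cells, with 1836 at an unadjusted p under 0.05, while 12 were called with the replicate number as a block over all arrays and 26 without the Nnm arrays numbered 2. The arrays of the 2 times did not overlap for 23.3% of the tested probe sets, where chance gives 10%. The metallothionein list lost its call with the block (camera adjusted p = 0.0780), and the probe set count was 4, 1 and 2 without Nnm replicate 2 of 24 h, Nnm replicate 3 of 24 h and control replicate 2 of 24 h.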

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

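Tests named here of the Nnm arrays numbered 2 and of the DNA replication list were chosen after the results were seen, while the other splits of the arrays were planned. Camera with a preset correlation called 11 lists for a difference between the Nnm effects at 48 h and 24 h, none of which was called by fry or with an estimated correlation, where the lowest adjusted p was 0.394. The median differences were 0.63 for DNA replication, 0.67 for homologous recombination and Fanconi repair, 0.34 for excision and direct repair, 0.34 for ribosome biogenesis and 0.89 for NF-kappaB and inflammatory cytokines. They were -0.74 for clustered histones, -0.46 for metallothioneins and zinc export, -0.33 for endoplasmic reticulum chaperones, -0.26 for lysosome and autophagy, -0.16 for oxidative phosphorylation and -0.14 for fatty acid oxidation. Without the Nnm arrays numbered 2 the calls for oxidative phosphorylation, ribosome biogenesis and fatty acid oxidation ended (camera adjusted p = 0.0886, 0.221 and 0.221), and with a block within each time that for fatty acid oxidation did (0.0557). The medians of these 3 lists without the arrays were -0.15, 0.28 and -0.19. In 3 of the 168 genes named for 24 h or 48 h, the only ones searched for this, every Nnm array moved one way at 24 h and the other way at 48 h, and limma did not call the difference between the effects, with an adjusted p of 0.780 for each. The difference was 1.41 in CDC45 and 1.24 in BLM, which were lower at 24 h and higher at 48 h, and -1.52 in SLC19A2, a thiamine transporter gene that was higher at 24 h and lower at 48 h. How many of the 168 genes would turn in this way by chance was not worked out, so the 3 are not read as an excess.

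Of 100 drawn splits of the 12 arrays within their times, 11 called as many lists for this difference, the real one included, and the highest other count was 13, so chance cannot be excluded for the count of lists. All splits described here exchange arrays across replicate numbers and so do not keep the pairing. The real grouping called 0 probe sets, so all 100 splits gave as many. The highest other split called 8101. It exchanged Nnm and control at 48 h alone, so that it measured the sum of both Nnm effects, which is a structure of the samples. With 6 arrays the splits number 10, too few for a share under 0.05. At 24 h the real grouping called 3366 probe sets and the highest other 0, and 1 of 10 splits gave as many. At 48 h these were 2323 and 0, and 1 of 10 splits. In control cells over time all 10 splits gave as many probe sets as the real count of 0. For lists, the real count and the highest other were 11 and 11 at 24 h, 9 and 12 at 48 h and 6 and 7 in control cells, and 2, 3 and 3 of 10 splits gave as many.

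The Nnm arrays numbered 2 lay near the control arrays at both times. A control array under an Nnm label is argued against, since Nnm replicate 2 gave 1232 called probe sets at 24 h and 398 at 48 h against control replicates 1 and 3 of its time, and control replicate 2 gave 0 in the same fits, where lone arrays are assumed to vary like the others, and since in 2 other fits, which change the count to 389 and 263 or to 16 and 7, each control array gave 0 too. Dilution of RNA like that of replicates 1 and 3 with control RNA was tested in 6 forms. In the last, an interval above 1 was set to argue against dilution, which was met at 24 h and not at 48 h. The distance from the best mixture was set against the largest distance among control arrays or between Nnm replicates 1 and 3. It was 1.47 (95% bootstrap interval 1.29 to 1.56) times as large at 24 h and 1.14 (0.972 to 1.29) times at 48 h. The intervals resample probe sets of 1 array as if independent and hold no spread between arrays. The one above 1 at 24 h therefore does not decide, and dilution stays open at both times. A weaker response in the same direction stays open. In replicates 1 and 3, 985 probe sets at 24 h and 815 at 48 h moved at least 4-fold. Of these, 81.1% and 90.8% moved the same way from control replicate 2 to Nnm replicate 2. Between control arrays it was at most 56.6% and 57.5%. Dilution would give such a share too. A lower dose or another state of these cultures stays open, and no biological explanation was tested.

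The DNA replication list had a median difference of 0.63 between the Nnm effects, which camera called at the preset correlation but not at an estimated one, and fry did not call (adjusted p = 0.205), with 0 of 24 members passing, so chance cannot be excluded. The Nnm arrays numbered 2 are argued against as the cause of this median, since the difference was 0.89 without them. A fall in control cells alone stays open, because the control replicates changed by -0.54, -0.43 and -0.25 from 24 h to 48 h and the Nnm replicates by 0.44, -0.24 and 0.60, so that Nnm replicate 2 fell with the controls and the other Nnm replicates did not. A difference in how Nnm acted on these genes at the 2 times is a hypothesis that these arrays do not settle.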

How the results depend on the processing

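Leaving out the Nnm arrays numbered 2, all 4 arrays numbered 2, or the Nnm arrays with a block were choices made after seeing the data, and the others were planned. Counts of called probe sets are given in the order 24 h, 48 h, difference of effects and control cells, against 3366, 2323, 0 and 0. Without the filter they were 848, 842, 2 and 1, with array weights 12093, 11202, 3899 and 94, and with the replicate number as a block over all arrays 6700, 5046, 0 and 12. A block within each time gave 2415, 2282 and 0, and for control cells the block over all arrays stands in its place with 12. Leaving out both Nnm arrays numbered 2 gave 10730, 9605, 2556 and 26, this with the block over all arrays 12917, 11847, 5300 and 2494, and leaving out all 4 arrays numbered 2 gave 9821, 8299, 941 and 0. Probe sets without the suffix x or s gave 1873, 1404, 0 and 1, 1 probe set per gene 2141, 1326, 0 and 0, a fold of at least 2 1657, 1217, 0 and 0, and an adjusted p under 0.01 113, 187, 0 and 0. The compared arrays alone gave 112, 115 and, for control cells, 4, and a t-test per probe set called 0 in these 3, with 5534, 5079 and 3103 at an unadjusted p under 0.05. A filter at log2 6 and median centring each gave 1 in control cells, and counts at 24 h and 48 h stayed within 1.5 times with them, with a further quantile normalization and with trend and robust eBayes. Calls higher and lower at 24 h were 1671 and 1695 with all arrays, 1708 and 1630 after a further quantile normalization and 1653 and 1775 after median centring. The array weights were 0.136 and 0.196 for the Nnm arrays numbered 2. Leaving out each array in turn gave 81 to 8683, 207 to 6117, 0 to 1028 and 0 to 4. The count at 24 h also fell, to 2264 to 2399, without a control array of 48 h, and that at 48 h, to 1414 to 1588, without one of 24 h, although these arrays are not in the contrast. The causes of these moves were not tested.

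Of the named genes called, 71 at 24 h and 76 at 48 h, none turned direction in the fits run for single genes. These left out array weights, the compared arrays alone, the t-test and the fit without probe sets of suffix x or s. With each gene represented by its probe set of the simplest suffix, 2 of the 71 and 7 of the 76 lost their call. Without Nnm replicate 1 or 3 of 24 h, 2 and 4 of the 71 kept their call, without control replicate 3 of 24 h 1 did, and without Nnm replicate 2 of 24 h 70 did. Without Nnm replicate 1 or 3 of 48 h 10 of the 76 kept it, and without Nnm replicate 2 of 48 h all 76 did. With a block within each time 47 and 62 kept it, without the filter 18 and 29, and with the block over all arrays all did. Of 35 and 34 named genes not called at 24 h and 48 h, 13 at each time gained a call with the block over all arrays and 5 and 4 with a block within each time. Apart from the lists named with each comparison, the block over all arrays ended no list call. Of the 11, 9, 11 and 6 list calls at 24 h, at 48 h, for the difference and in control cells, leaving out the filter ended 2, 0, 3 and 1, a further quantile normalization 0, 1, 1 and 1, and the median over the probe sets of a gene 0, 1, 1 and 0. The lists that lost their call without the filter were ATF4 and glucocorticoid targets at 24 h, chaperones, fatty acid oxidation and lysosome for the difference, and ATF4 in control cells. The other 2 settings ended fatty acid oxidation at 48 h, and for the difference fatty acid oxidation and lysosome, and quantile normalization ended ATF4 in control cells. Leaving out each array in turn ended 0 to 2, 0 to 3, 0 to 4 and 0 to 2 calls, and added 0 to 1, 0 to 3, 0 to 4 and 0 to 2. Leaving out all 4 arrays numbered 2 ended 1, 2, 3 and 1. Without the filter 2 lists were added at 48 h, DNA replication and chaperones, quantile normalization added lysosome at 24 h, and fry added glucocorticoid targets at 48 h. The mitosis list, not called for the difference of effects with a median of 0.01, was called in opposite directions without single arrays, higher without Nnm replicate 1 of 48 h (0.34, camera adjusted p = 0.00357) and lower without Nnm replicate 2 of 48 h (-0.29). Of 147 calls of named genes 67 had another tested probe set, which was called the same way for 42 and the other way for 1, LIG3 at 24 h. Signal near background limits genes whose brighter group lay close to log2 4, and their order was not read.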

Other observations

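Tests in this part were chosen after the data were seen. In Nnm replicates 1, 2 and 3 the interferon list had a median change of 0.61, 0.70 and 0.58 at 24 h and 0.73, 0.78 and 0.71 at 48 h, and the ribosome biogenesis list of -0.77, -0.62 and -0.66 at 24 h and -0.44, -0.19 and -0.47 at 48 h. The clustered histones had -1.35, -0.90 and -0.98 at 48 h. The ATF4 list had 1.24, -0.19 and 0.97 at 24 h. TXNIP, called at 24 h with a rise of 2.77 from 9.55 ± 0.37 to 12.32 ± 0.23 (adjusted p = 0.0252), stood at 12.43, 12.05 and 12.48 in the 3 Nnm arrays of 24 h. RNF150 stood at 10.19, 2.60 and 10.61 in the same arrays, with a control mean of 2.59, while SLC16A14 stood at 10.62, 7.53 and 10.75. GDF15 stood at 13.03, 9.35 and 12.75 against control arrays at 10.38, 10.51 and 10.50.

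For the mean Nnm effect over both times, the 24 h and 48 h arrays of a replicate and arm were averaged first, since Nnm arrays that share a number correlate at 0.508 to 0.669 and are not independent. Over these 6 values limma called 1024 probe sets, 592 higher and 432 lower, and with a replicate block it called 0, with 8772 at an unadjusted p under 0.05. A fit that counts all 12 arrays as independent called 8101.

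Without the Nnm arrays numbered 2 camera called 11 lists at each time, against 11 at 24 h and 9 at 48 h with all arrays. Some of them were not called in the planned fit with all arrays. At 24 h these were lysosome and autophagy genes, with 10 of 17 risen (camera adjusted p = 0.00283), and immediate early genes, with 11 of 16 risen and 2 fallen (0.0458). At 48 h they were the ATF4 list, with 14 of 26 risen (0.00288), heat shock genes, with 8 of 13 risen (0.0258), immediate early genes, with 11 of 16 risen and 1 fallen (0.00737), and mitosis genes, with 8 of 21 fallen (0.0320). None was called with an estimated correlation (adjusted p = 0.481 for both at 24 h, and 0.655, 0.491, 0.491 and 0.655 at 48 h).

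Lists that camera called at neither time in the planned fit with all arrays were p53 targets, mitosis, hypoxia and glycolysis, endoplasmic reticulum chaperones, heat shock, immediate early genes, NF-kappaB and inflammatory cytokines, kidney injury, xenobiotic metabolism, proximal tubule function, cytosolic ribosomal proteins, matrix and TGF-beta response, epithelial junctions and keratins, BCL2 family and apoptosis, lysosome and autophagy, and the markers of fibroblasts, podocytes and distal nephron. Their single calls included the aryl hydrocarbon receptor target TIPARP, which fell by 0.85 at 24 h and 1.43 at 48 h, MIOX, a proximal tubule enzyme gene that fell by 0.94 and 1.23, and the basement membrane collagen gene COL4A1, which fell by 1.12 at 48 h. The hypoxia list went both ways at 24 h, where ANKRD37 rose by 1.70 and KDM3A by 1.22 while PDK1 fell by 0.92. Of the 14 cytosolic ribosomal protein genes 0 were called at either time.

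Of the 62 control probe sets of the manufacturer, 15 lay above all control arrays in all 3 Nnm arrays at 24 h and 2 at 48 h, and 0 did so at both times. Chance gives 5% in one direction for independent probe sets. Most of the 15 read the same few transcripts, bioB, bioC, bioD and cre, so that share does not apply to them. Only 1 lay below all control arrays at each time, the 3' probe set of ACTB, with changes of -0.28 and -0.23. The log2 difference between the 3' and 5' probe sets of ACTB was 1.09 to 1.19 in the 4 arrays numbered 2, controls included. In the arrays numbered 1 and 3 it was 0.89 to 0.97 with Nnm and 0.80 to 0.83 in controls, and the Nnm array was higher in 5 of 6 same-numbered pairs.

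Earlier forms of the tests of the Nnm arrays numbered 2 gave these values, and those of dilution were not used to decide. Against all 3 control arrays of its time the array gave 389 called probe sets at 24 h and 263 at 48 h, or 16 and 7 with the other arrays kept in their groups. Of the called lists, chosen with replicate 2 included, 3 of 11 at 24 h and 7 of 9 at 48 h lay off the best mixture by over 2 times the largest distance of a control array. The distance from the mixture was 2.08 (95% bootstrap interval 1.83 to 2.31) and 1.42 (1.20 to 1.54) times that of control replicate 2 alone, which leaves out the spread between treated cultures. In the fifth form of the dilution test, with the largest distance of a control array as the only reference, it was 1.49 (1.31 to 1.60) and 1.39 (1.16 to 1.5004), with both intervals above 1. The reference was widened to the distance between Nnm replicates 1 and 3 after this outcome was seen. All intervals in this paragraph resample probe sets of 1 array per time as if independent. Steps of probe sets off in control cells, many near the floor in replicate 2, spread 3.49 (2.00 to 5.74) and 4.35 (1.49 to 11.2) times as much as between Nnm replicates 1 and 3, or 3.82 and 15.3 times in the 12 and 9 brighter ones.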
